A study of Hordeum vulgare with 12 samples.

How the data were processed

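Poly(A) RNA of 12 barley crown libraries, 4 times with 3 independent biological replicates of 5 pooled crowns each, was sequenced in paired reads of 150 bases with a directional kit, per the labels. The p-values below measure differences between such pools of one experiment. The submitters' processing notes name bcl2fastq, HISAT2 2.0.5, SAMtools and Subread 1.5.2. The genome build and the strand and multi-mapping settings of the counting are not given in the sources used here; gene identifiers carry the prefix HORVU.MOREX.r2, and coordinates are those of the deposited files. Raw read counts per gene for 63658 genes were deposited by the authors without normalization, and the same 12 columns of counts stand in both deposited tables. The FPKM values in the authors' deposited table are 1 value per time, made by the authors from the mean count, the gene length and the mean total of reads (largest difference from that formula 3.27e-11). The log2 fold changes in the authors' deposited table were made by the authors between pairs of times with a test and tool that are not stated. The adjusted p-values in the same deposited table were also made by the authors and cover 6 comparisons. The FPKM values were not used for tests, since they hold no replicates.

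Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. The total of reads, a row of the authors' deposited table, was left out of library sizes and tests and used only for the assigned share. Genes with enough counts by filterByExpr (minimum count 10, minimum total 15) were kept, 24920 in all, with at least 99.9% of the assigned reads of each library, and 26328 genes had no read. Libraries were scaled by TMM. Differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in 1 model of the 4 times with 8 residual and a median of 3.59 prior degrees of freedom, and called at an adjusted p under 0.05. Log2 CPM, counts scaled to library size by edgeR's cpm function, used a prior count of 2. In a library, 3 counts correspond to 0.0882 to 0.186 CPM, and this floor and the counting interval cover counting error alone.

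Before the data were examined, the tests, the alternatives, 33 gene lists (by words in gene descriptions) and the rule for named genes were fixed. The lists cover Aux/IAA, GH3, SAUR, auxin response factor, LOB domain, auxin transport, auxin synthesis and reception, AP2-like and PLETHORA, ethylene response factor, WUSCHEL-related, KNOX and BEL, GRAS, WRKY, cytokinin response and synthesis, ethylene synthesis, gibberellin oxidase, jasmonate, cyclin, core histone, expansin, ribosomal protein, clock, photosystem, heat shock, glutathione S-transferase, UDP-glycosyltransferase, cytochrome P450, peroxidase, grain, xylem, phloem and root hair genes. After the descriptions were read and before any test, the words of 6 lists were amended: Aux/IAA, GRAS, ethylene response factor, core histone, clock and grain. For Aux/IAA the words were applied to the descriptions of the Arabidopsis and rice homologs in place of the gene's own. For the others unrelated matches were excluded. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists and 3 comparisons with 0 h, and apart from these over the 3 other comparisons. An estimated correlation and fry were run beside it.

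Named genes are, in each comparison with 0 h, the 6 largest rises and 6 largest falls among described genes that passed with a mean of at least 1 CPM and all 3 later libraries on the same side of all 3 at 0 h. To these come the 2 members of each list with the smallest p and the homologs of rice and maize crown-root genes (CRL1, CRL4, CRL5, ARL1, RTCS, PLT, WOX11, WOX5, SHR and SCR) by symbol. By this last rule homologs of CRL1, CRL4, CRL5 (second homologs only) and WOX11 alone were named, and of QHB none was tested. A first or second homolog is a barley gene for which the authors' deposited table lists the rice gene first or second.

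Whether replicate numbers pair libraries across times was checked by the correlation of residuals. Of 18 pairs with the same number 17 exceeded 0.1, from 0.0958 to 0.674, against -0.593 to 0.268 for other pairs, and 12 of 12 libraries correlated best with a library of their own number. Every pair exceeded 0.1 in each comparison except 1 h against 0 h, where the lowest was 0.0958. The value with the replicate number as a block is printed beside each comparison that made calls, the time course and the overlap. This use of the check was settled after counts of calls had been seen. Replicates were not duplicates of each other (chi-square per degree of freedom 16.6 to 91.7).

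The procedure was tested on simulated data with 200 of 24920 genes changed. edgeR recovered 0, 20, 68 and 82% of genes changed by 1.5, 2, 4 and 8 times at 30 min, 2, 32, 66 and 92% at 1 h and 0, 16, 84 and 84% at 3 h, with 8.60, 9.43 and 4.17% of calls false. DESeq2 recovered 12, 46, 78 and 86%, 12, 44, 80 and 96%, and 10, 42, 90 and 88%, with 27.9, 28.8 and 33.3% false. The simulated counts took their dispersions from edgeR, and only for edgeR did a recovered gene need the right direction. The rates of the 2 tools are therefore not on equal terms and need not hold for the real libraries. A list raised at 3 h had a camera p of 9.37e-15, and 0, 1 and 0 of 32 random lists had a p under 0.05. The simulated genes were drawn independently of each other and without replicate effects. These lists therefore do not test the preset correlation for genes that vary together.

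Alternatives were relative log expression scaling, no filter, a stricter filter (1 CPM in 3 libraries), the replicate block (6 residual degrees of freedom), DESeq2, the 2 groups alone, a minimum log2 fold change of 1, and leaving out each library in turn. Leaving out the 3 libraries of lowest assigned share was added after seeing the data. The enrichment of gene families was also not fixed in advance.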

Results

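RNA of barley crowns (Hordeum vulgare, cultivar Golden Promise) was sequenced in a crown-root inducible system, in which the formation of crown roots, the shoot-borne roots of cereals, is first held back and then started by auxin. Seedlings were kept on 50 µM NPA, an inhibitor of polar auxin transport, and then moved to 50 µM 1-NAA, a synthetic auxin. The crown, the 2 mm junction between roots and stem, was collected before the change of solution (0 h) and 30 min, 1 h and 3 h after it. Each of the 4 times had 3 libraries, described in the labels as independent biological replicates, and each library was a pool of 5 crowns. The comparisons ask which genes respond first when crown roots are induced. No untreated crowns of the same age were sampled at 30 min, 1 h or 3 h, so the auxin, the removal of NPA, the change of solution and the time of day changed together in every comparison with 0 h.

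The deposited counts assigned to genes were 16093892, 26381453 and 34019480 at 0 h for replicates 1 to 3, 18502420, 23519719 and 25438445 at 30 min, 21190922, 27851950 and 27984548 at 1 h and 22710691, 25664867 and 23737664 at 3 h. The share of all reads assigned to genes was 66.4%, 64.8% and 56.0% in replicate 1 of 0 h, 30 min and 3 h and between 71.9% and 78.4% in the other 9 libraries. In a principal component analysis of 2000 genes, the first component (31.2% of the variance) held the replicate 3 libraries between 20.5 and 40.7. The replicate 1 libraries lay between -48.2 and -21.2 on it. The second component (22.9%) held the 3 h libraries between 29.9 and 50.7 and the other 9 libraries between -26.8 and -0.175.

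Over the whole time course, 574 of 24920 tested genes (2.30%) changed by edgeR's F-test over the 4 times. Of these, 368 had their highest mean at 3 h, 72 at 1 h, 80 at 30 min and 54 at 0 h, and 222 had their lowest mean at 0 h and 188 at 3 h. Among the genes with the highest mean at 3 h were an auxin-inducible GH3.3 gene, an auxin-responsive (Aux/IAA) gene and a WUSCHEL-related homeobox gene, and the plot of 6 genes by library shows their counts. Of the 574 genes, 455 also passed the comparison of 3 h with 0 h and 119 did not. Without replicate 3 of 3 h the count was 297 and without replicate 2 of 3 h it was 331. With the replicate number as a block it was 1446, and DESeq2 called 1572.

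**Figure D1:**
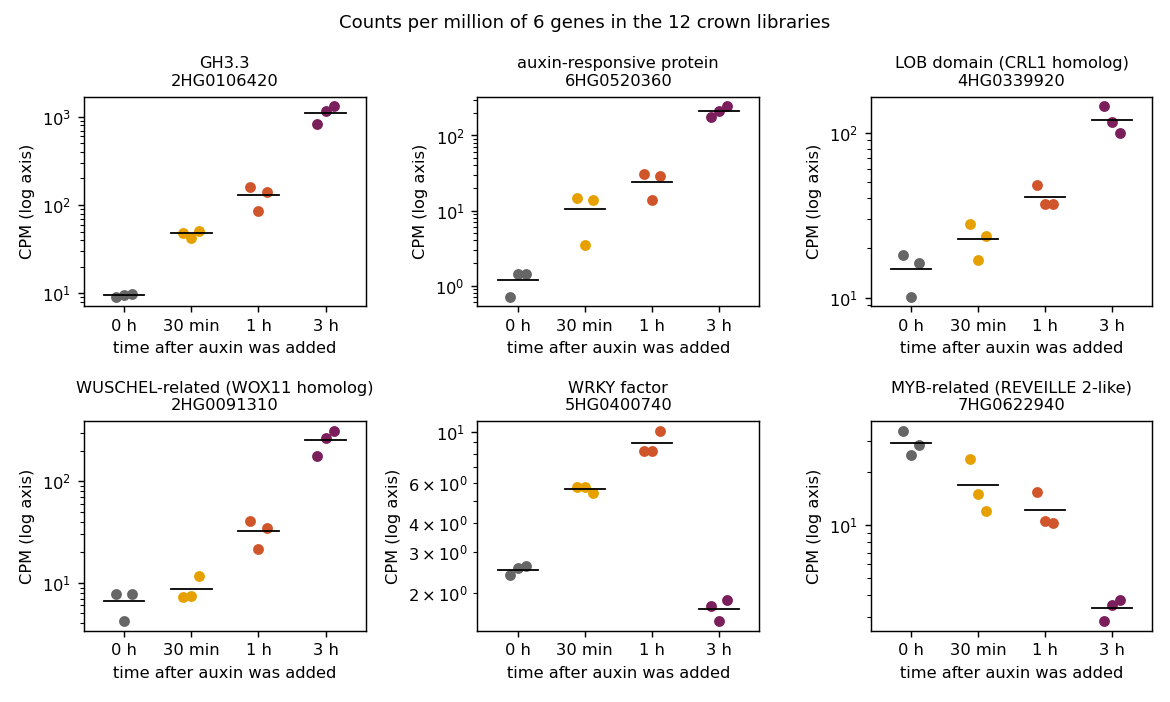
Counts scaled to library size (CPM, log axis) of 6 genes in each of the 12 libraries by time after auxin was added; dots from left to right are replicates 1 to 3 and lines are means of 3. The GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 rises from 9.46 to 1107 CPM between 0 h and 3 h, the WRKY gene HORVU.MOREX.r2.5HG0400740.1 has its highest mean, 8.89 CPM, at 1 h, and the MYB-related gene HORVU.MOREX.r2.7HG0622940.1 falls from 29.3 to 3.38 CPM.

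At 30 min against 0 h, 1 gene rose. It was the GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 (chromosome 2H, 121197894 to 121199873), one of a family of enzymes that join auxin to amino acids. Its count rose from 9.46 ± 0.372 CPM (SD, n = 3) to 47.5 ± 4.32 CPM (n = 3), a log2 fold change of 2.33 ± 0.235 (SE, edgeR adjusted p = 0.0133). Larger estimates did not pass: the auxin-responsive gene HORVU.MOREX.r2.6HG0520360.1, similar to Arabidopsis IAA4, stood 3.11 ± 0.52 above 0 h (adjusted p = 0.276) and the jasmonate ZIM-domain (JAZ) gene HORVU.MOREX.r2.7HG0555360.1 stood 3.77 ± 0.634 above it (adjusted p = 0.276). The heat shock factor gene HORVU.MOREX.r2.5HG0423600.1 was at 4.96 ± 1.12 (adjusted p = 0.416). With 0 genes lower by edgeR, 1095 genes of either direction had an unadjusted p under 0.05, where 1246 would with no change at all, and DESeq2 called 91 genes higher and 3 lower. With the replicate number as a block, 3 genes rose: the GH3.3 gene (adjusted p = 0.00709), the JAZ gene HORVU.MOREX.r2.7HG0555360.1 (adjusted p = 0.0192) and the cytochrome P450 gene HORVU.MOREX.r2.4HG0296400.1, similar to Arabidopsis CYP94C1 (adjusted p = 0.0241). The adjusted p of the GH3.3 gene was 0.173, 0.205 and 0.0616 without replicates 1, 2 and 3 of 0 h, and 0.0693 and 0.091 without replicates 1 and 3 of 30 min. The count of genes was 0 without replicate 1 or 2 of 0 h or replicate 1 or 3 of 30 min. Without replicate 3 of 0 h the 1 gene was the EF-hand gene HORVU.MOREX.r2.7HG0550710.1, and without replicate 2 of 30 min the count was 3, with the GH3.3 gene, HORVU.MOREX.r2.6HG0520360.1 and the gene HORVU.MOREX.r2.2HG0088620.1. The EF-hand gene, like every gene below that is named only because a count was 5 or fewer, was chosen after its values were seen.

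As a list, the 52 jasmonate genes lay higher at 30 min, with a median log2 fold change of 0.30 and 40 members above 0 (camera adjusted p = 4.62e-11, adjusted p = 0.0865 with an estimated correlation). None of them passed edgeR over all genes and 14 rose when adjusted over the list alone. The 12 ethylene synthesis genes had a median of 0.24 with all 12 above 0 (adjusted p = 1.36e-06, adjusted p = 0.0469 with an estimated correlation). Adjusted over the list alone, 3 of them rose, the ACC oxidase genes HORVU.MOREX.r2.1HG0017380.1 and HORVU.MOREX.r2.1HG0017390.1 and the ACC synthase gene HORVU.MOREX.r2.2HG0154390.1. The gene HORVU.MOREX.r2.1HG0017380.1, for the last enzyme of ethylene synthesis, went from 20.4 ± 4.64 to 56.0 ± 10.3 CPM (n = 3 each). Its log2 fold change of 1.45 ± 0.2 did not pass over all genes (adjusted p = 0.15). The 85 WRKY transcription factor genes had a median of 0.23 (adjusted p = 3.77e-06, adjusted p = 0.0865 with an estimated correlation). Adjusted over the list alone, 4 of them rose: HORVU.MOREX.r2.5HG0400740.1, HORVU.MOREX.r2.6HG0471210.1, HORVU.MOREX.r2.7HG0616260.1 and HORVU.MOREX.r2.7HG0616250.1, the last at 3.47 ± 0.609 (adjusted p = 0.314 over all genes). The 13 gibberellin oxidase genes had a median of 0.42 (adjusted p = 0.000588, adjusted p = 0.274 with an estimated correlation). Of these, HORVU.MOREX.r2.3HG0240680.1, HORVU.MOREX.r2.5HG0446540.1 and HORVU.MOREX.r2.6HG0494570.1 rose adjusted over the list alone. These medians moved by over 1.5 times without single libraries. The jasmonate median was 0.57 without replicate 3 of 0 h. The ethylene synthesis median was 0.39 without replicate 1 of 0 h. The WRKY median was 0.35 without replicate 1 of 0 h and 0.12 without replicate 1 of 30 min. The gibberellin oxidase median was 0.88 and 0.81 without replicates 1 and 2 of 0 h, 0.67 without replicate 2 of 30 min, 0.68, 0.68 and 0.68 without replicates 1, 2 and 3 of 1 h, and 0.68 and 0.68 without replicates 1 and 2 of 3 h.

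Smaller shifts passed the same test at 30 min. Of the 12 list calls at 30 min 1 also passed with an estimated correlation, and fry passed 2 of the 33 lists. When the 12 libraries were regrouped at random, the preset correlation still gave 4 to 42 list calls over the 3 comparisons with 0 h. Their median was 19 over 99 other groupings, against 42 in the real one. A single list call at the preset correlation is therefore weak evidence by itself. Heat shock and chaperone genes (253) had a median of 0.07 (adjusted p = 0.000197, adjusted p = 0.279 with an estimated correlation). GH3 genes (9) had a median of 0.20 (adjusted p = 0.00932, adjusted p = 0.435 with an estimated correlation), and 2 rose adjusted over the list alone, HORVU.MOREX.r2.2HG0106420.1 and HORVU.MOREX.r2.3HG0242100.1. SAUR genes (45), a family of small auxin-induced RNAs, had a median of 0.17 (adjusted p = 0.0229, adjusted p = 0.256 with an estimated correlation). Glutathione S-transferase genes (87) had a median of 0.12 (adjusted p = 0.0298, adjusted p = 0.559 with an estimated correlation). Ethylene response factor genes (81) had a median of 0.06 (adjusted p = 0.0329, adjusted p = 0.382 with an estimated correlation), and HORVU.MOREX.r2.2HG0157200.1 rose adjusted over the list alone. Auxin-responsive Aux/IAA genes (19) had a median of 0.13 (adjusted p = 0.0462, adjusted p = 0.622 with an estimated correlation), and HORVU.MOREX.r2.6HG0520360.1 rose adjusted over the list alone. The ribosomal protein list (152) was lower, with a median of -0.11 (adjusted p = 3.87e-06, adjusted p = 0.409 with an estimated correlation). So was the photosystem and light-harvesting list (102), also with a median of -0.11 (adjusted p = 1.72e-05, adjusted p = 0.279 with an estimated correlation). Without replicate 1 of 0 h the adjusted p was 0.268 for GH3, 0.452 for Aux/IAA, 0.247 for ethylene response factors and 0.0997 for the photosystem list. Without replicate 2 of 0 h it was 0.154 for SAUR and 0.383 for both ethylene response factors and glutathione S-transferases. Without replicate 3 of 30 min it was 0.266 for GH3, 0.467 for Aux/IAA, 0.314 for ethylene response factors and 0.224 for glutathione S-transferases. Without replicate 1 of 30 min it was 0.178 for SAUR and 0.541 for glutathione S-transferases, without replicate 2 of 3 h 0.0557 for Aux/IAA, and without replicate 3 of 1 h 0.05 for ethylene response factors. Medians also moved by over 1.5 times without single libraries. The heat shock median was 0.12 without replicate 1 of 0 h and 0.12 without replicate 3 of 30 min. The GH3 median was 0.0308 and 0.65 without replicates 1 and 3 of 0 h and 0.37, 0.0692 and 0.0881 without replicates 1, 2 and 3 of 30 min. The SAUR median was 0.39 and 0.0392 without replicates 1 and 2 of 0 h and 0.0988 and 0.28 without replicates 1 and 2 of 30 min. The glutathione S-transferase median was 0.0682, 0.24 and 0.0699 without replicates 1, 2 and 3 of 30 min. The ethylene response factor median was 0.13 and 0.22 without replicates 1 and 3 of 0 h and 0.18 and 0.0095 without replicates 1 and 3 of 30 min. The Aux/IAA median was 0.0628 and 0.37 without replicates 1 and 3 of 0 h and 0.27 without replicate 1 of 30 min. The ribosomal protein median was -0.0578 and -0.17 without replicates 2 and 3 of 0 h. The photosystem median was -0.0011 and -0.21 without replicates 1 and 2 of 0 h and -0.18 and -0.0616 without replicates 1 and 2 of 30 min.

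At 1 h against 0 h, 24 genes rose and 0 fell. The auxin-responsive gene HORVU.MOREX.r2.6HG0520360.1 (6H, 556882099 to 556882739) went from 1.18 ± 0.406 to 24.3 ± 9.28 CPM (n = 3 each), a log2 fold change of 4.30 ± 0.531 (adjusted p = 0.0161). The GH3.3 genes HORVU.MOREX.r2.2HG0106420.1 and HORVU.MOREX.r2.3HG0242100.1 rose by 3.77 ± 0.248 (adjusted p = 0.000131) and 2.70 ± 0.396 (adjusted p = 0.03). The Aux/IAA genes HORVU.MOREX.r2.1HG0021490.1 and HORVU.MOREX.r2.3HG0199050.1, similar to Arabidopsis IAA17, rose by 1.70 ± 0.267 (adjusted p = 0.0445) and 1.55 ± 0.236 (adjusted p = 0.0356). The Aux/IAA gene HORVU.MOREX.r2.3HG0238900.1, similar to IAA26, rose by 0.95 ± 0.12 (adjusted p = 0.0161). Among transcription factor genes, the bZIP gene HORVU.MOREX.r2.7HG0557340.1 rose by 2.75 ± 0.418 (adjusted p = 0.0356), the MYB gene HORVU.MOREX.r2.2HG0090570.1 by 2.63 ± 0.399 (adjusted p = 0.0356) and the WRKY gene HORVU.MOREX.r2.5HG0400740.1, similar to Arabidopsis WRKY40, by 1.82 ± 0.174 (adjusted p = 0.00378). The WUSCHEL-related gene HORVU.MOREX.r2.2HG0091310.1 (2H, 32750309 to 32752599) has rice WOX11 as its first listed rice homolog in the authors' deposited table. It went from 6.55 ± 2.05 to 32.3 ± 9.58 CPM (n = 3 each), a log2 fold change of 2.30 ± 0.329 (adjusted p = 0.0292). Beside the 0 lower genes by edgeR, 1432 genes of either direction had an unadjusted p under 0.05 (1246 would with no change), and DESeq2 called 101 higher and 14 lower. With the replicate number as a block 66 genes passed, 62 higher and 4 lower, among them all 24.

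Of the 24 genes, the GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 and the WRKY gene HORVU.MOREX.r2.5HG0400740.1 passed in each of the 12 fits that left out 1 library, with highest adjusted p of 0.00407 and 0.0319. The other 9 that the rule for named genes picked had highest adjusted p between 0.119 and 0.278. Of these, 9, 7 and 8 lost the call without replicates 1, 2 and 3 of 0 h, 1, 2 and 2 without those of 30 min, 9, 4 and 9 without those of 1 h, and 7 and 4 without replicates 2 and 3 of 3 h. The count of genes at 1 h was 5, 6 and 5 without replicates 1, 2 and 3 of 0 h, 3, 14 and 3 without replicates 1, 2 and 3 of 1 h, and 9 without replicate 2 of 3 h. The 3 genes, in both fits, were the GH3.3 gene HORVU.MOREX.r2.2HG0106420.1, the WRKY gene HORVU.MOREX.r2.5HG0400740.1 and the homeobox-leucine zipper gene HORVU.MOREX.r2.2HG0157290.1. Without replicate 1 of 0 h the lysine/histidine transporter gene HORVU.MOREX.r2.2HG0155730.1 and the F-box gene HORVU.MOREX.r2.4HG0316440.1 joined them. Without replicate 3 of 0 h the ACC oxidase gene HORVU.MOREX.r2.1HG0017380.1 and the EF-hand gene HORVU.MOREX.r2.7HG0550710.1 did.

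Among the lists at 1 h, the Aux/IAA genes had a median of 0.74 with 18 of 19 above 0 (adjusted p = 4.62e-11, adjusted p = 0.0886 with an estimated correlation). Over all genes the 4 named above rose, and HORVU.MOREX.r2.1HG0071140.1 joined them adjusted over the list alone. GH3 genes had a median of 0.25 (adjusted p = 4.68e-05, adjusted p = 0.25 with an estimated correlation), with 2 higher over all genes and HORVU.MOREX.r2.1HG0054200.1 added when adjusted over the list alone. SAUR genes had a median of 0.23 (adjusted p = 0.000827, adjusted p = 0.111 with an estimated correlation), and HORVU.MOREX.r2.5HG0417310.1, HORVU.MOREX.r2.5HG0417400.1 and HORVU.MOREX.r2.5HG0417410.1 rose adjusted over the list alone. WUSCHEL-related homeobox genes (8) had a median of 0.40 (adjusted p = 0.0013, adjusted p = 0.0803 with an estimated correlation). Without a filter on low counts the median turned to -0.0235, with the test still upward (adjusted p = 0.0468). The genes HORVU.MOREX.r2.2HG0170340.1 and HORVU.MOREX.r2.4HG0315980.1 rose with HORVU.MOREX.r2.2HG0091310.1 adjusted over the list alone. LOB domain genes (22) had a median of 0.17 (adjusted p = 0.00841, adjusted p = 0.101 with an estimated correlation), and HORVU.MOREX.r2.4HG0277770.1, HORVU.MOREX.r2.4HG0339920.1, HORVU.MOREX.r2.5HG0385220.1 and HORVU.MOREX.r2.6HG0523370.1 rose adjusted over the list alone. Ethylene synthesis genes had a median of 0.43 (adjusted p = 2.47e-05, adjusted p = 0.0469 with an estimated correlation). The ACC oxidase gene HORVU.MOREX.r2.1HG0017380.1 passed over all genes (1.44 ± 0.2, adjusted p = 0.0244), and HORVU.MOREX.r2.1HG0017390.1 and HORVU.MOREX.r2.2HG0154390.1 rose with it adjusted over the list alone. Gibberellin oxidases had a median of 1.06 (adjusted p = 6.06e-05, adjusted p = 0.218 with an estimated correlation), with HORVU.MOREX.r2.1HG0019640.1, HORVU.MOREX.r2.3HG0240680.1 and HORVU.MOREX.r2.5HG0446540.1 higher adjusted over the list alone. Jasmonate genes had a median of 0.33 (adjusted p = 8.19e-05, adjusted p = 0.274 with an estimated correlation), with HORVU.MOREX.r2.2HG0103320.1 and HORVU.MOREX.r2.5HG0398310.1 higher adjusted over the list alone. WRKY genes had a median of 0.22 (adjusted p = 0.00044, adjusted p = 0.2 with an estimated correlation), with HORVU.MOREX.r2.5HG0400740.1 and HORVU.MOREX.r2.5HG0400750.1 higher adjusted over the list alone. Cytokinin synthesis genes had a median of 0.28 (adjusted p = 0.0135, adjusted p = 0.306 with an estimated correlation), with HORVU.MOREX.r2.1HG0033760.1 and HORVU.MOREX.r2.3HG0222470.1 higher adjusted over the list alone. Heat shock genes had a median of 0.08 (adjusted p = 0.00776, adjusted p = 0.432 with an estimated correlation), and the DnaJ gene HORVU.MOREX.r2.7HG0609890.1 rose over all genes and adjusted over the list alone. Ethylene response factors had a median of 0.14 (adjusted p = 0.0471, adjusted p = 0.409 with an estimated correlation) and the 7 circadian clock genes 0.24 (adjusted p = 0.0484, adjusted p = 0.497 with an estimated correlation). Lower at 1 h were ribosomal protein genes (median -0.16, adjusted p = 1.37e-08, adjusted p = 0.294 with an estimated correlation). Photosystem genes had a median of -0.18 (adjusted p = 5.75e-06, adjusted p = 0.274 with an estimated correlation), with HORVU.MOREX.r2.6HG0460170.1 lower adjusted over the list alone. The 174 core histone genes had a median of -0.17 (adjusted p = 0.000111, adjusted p = 0.76 with an estimated correlation). Some of these calls were lost without 1 library. The adjusted p of the core histone list was 0.569 without replicate 2 of 0 h. Without replicate 3 of 1 h its median was -0.0555, with the test turned upward (adjusted p = 0.995). The cytokinin synthesis list had 0.133 without replicate 1 of 1 h and 0.169 without replicate 3 of 0 h, the heat shock list 0.186 without replicate 1 of 1 h and the WRKY list 0.051 without replicate 2 of 0 h. For ethylene response factors it was 0.12 and 0.307 without replicates 1 and 2 of 0 h and 0.0506, 0.0686 and 0.0563 without replicates 1, 2 and 3 of 1 h. For the clock genes it was 0.108, 0.0509 and 0.136 without replicates 1 to 3 of 0 h and 0.0568, 0.0521 and 0.0647 without replicates 1 to 3 of 30 min. Without replicates 2 and 3 of 1 h it was 0.0832 and 0.547, and without replicate 3 of 3 h it was 0.054. Medians at 1 h moved by over 1.5 times without single libraries. The Aux/IAA median was 0.44 without replicate 1 of 0 h. The GH3 median was 0.16 and 0.60 without replicates 1 and 3 of 0 h and 0.50 without replicate 1 of 1 h. The SAUR median was 0.46 without replicate 1 of 0 h. The WUSCHEL-related median was 0.65 without replicate 2 of 0 h. The LOB domain median was 0.32 without replicate 3 of 0 h and 0.0751 and 0.28 without replicates 2 and 3 of 1 h. The ethylene synthesis median was 0.28 without replicate 1 of 1 h. The gibberellin oxidase median was 0.54 without replicate 3 of 0 h and 0.57 without replicate 2 of 1 h. The jasmonate median was 0.57 without replicate 3 of 0 h and 0.20 and 0.21 without replicates 2 and 3 of 1 h. The WRKY median was 0.14 without replicate 2 of 0 h and 0.11 without replicate 1 of 1 h. The cytokinin synthesis median was 0.15 without replicate 3 of 0 h and 0.11 without replicate 1 of 1 h. The heat shock median was 0.0397 and 0.14 without replicates 1 and 3 of 1 h. The ethylene response factor median was 0.34 without replicate 3 of 0 h. The clock median was 0.0048 without replicate 3 of 1 h. The photosystem median was -0.0781 without replicate 1 of 0 h. The core histone median was -0.0884, -0.0439 and -0.29 without replicates 1, 2 and 3 of 0 h and -0.0555 without replicate 3 of 1 h.

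**Figure D2:**
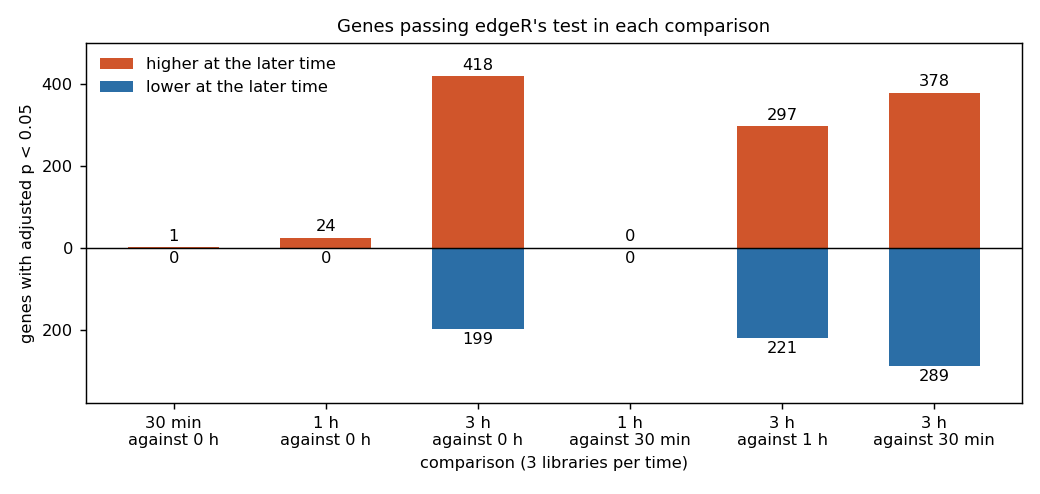
Number of genes with an adjusted p under 0.05 by edgeR in each of the 6 comparisons between times (3 libraries per time), higher genes as bars above 0 and lower genes below. The comparisons with 3 h hold 418 and 199, 297 and 221, and 378 and 289 genes, and the comparisons among 0 h, 30 min and 1 h at most 24.

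By 3 h, 617 genes differed from 0 h, 418 higher and 199 lower, and 350 and 139 of them by a log2 fold change of at least 1. The GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 reached 1107 ± 255 CPM (n = 3), a log2 fold change of 6.87 ± 0.285 (adjusted p = 7.24e-07). The GH3.3 gene HORVU.MOREX.r2.3HG0242100.1 (3H, 505959452 to 505963259) rose by 6.48 ± 0.458 (adjusted p = 2.02e-05) and the auxin-responsive gene HORVU.MOREX.r2.6HG0520360.1 by 7.43 ± 0.59 (adjusted p = 5.18e-05). A gene annotated as an auxin canalization protein, HORVU.MOREX.r2.4HG0346860.1, rose by 6.15 ± 0.575 (adjusted p = 0.000146). The gene HORVU.MOREX.r2.7HG0552630.1, similar to the Arabidopsis growth regulator PRE6, was counted 2 times at 0 h and 473 times at 3 h over 3 libraries each, a ratio of 258 (95% counting interval 71.1 to 2139, fitted adjusted p = 0.000996). With the replicate number as a block 1269 genes passed, 738 higher and 531 lower, among them all 617, and DESeq2 called 1086. Without replicate 3 of 3 h the count was 374 and without replicate 3 of 0 h it was 375.

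Members of several auxin gene families rose at 3 h. Of 19 Aux/IAA genes, repressors of auxin signalling, 11 rose (13 adjusted over the list alone). Their median was 1.60 (adjusted p = 2.47e-20, adjusted p = 0.0469 with an estimated correlation). Of 45 SAUR genes, 12 rose and 0 fell by edgeR over all genes. The counts were 18 higher and 3 lower (HORVU.MOREX.r2.7HG0603260.1, HORVU.MOREX.r2.7HG0610860.1 and HORVU.MOREX.r2.7HG0610870.1) adjusted over the list alone. The SAUR median was 0.52 (adjusted p = 4.38e-08, adjusted p = 0.0469 with an estimated correlation), and HORVU.MOREX.r2.5HG0416900.1 rose by 2.22 ± 0.271 (adjusted p = 0.000841), in a tandem group on chromosome 5H whose copies may share reads. In the GH3 list HORVU.MOREX.r2.2HG0106420.1, HORVU.MOREX.r2.3HG0242100.1 and HORVU.MOREX.r2.1HG0054200.1 rose, over all genes and adjusted over the list alone (median 0.69, adjusted p = 3.77e-06, adjusted p = 0.2 with an estimated correlation). Of 20 auxin transport genes 6 rose (8 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.000178, adjusted p = 0.218 with an estimated correlation). Among them were the auxin efflux carrier genes HORVU.MOREX.r2.3HG0236360.1, similar to PIN8 (2.51 ± 0.188, adjusted p = 3.06e-05), and HORVU.MOREX.r2.4HG0297660.1 (1.92 ± 0.199, adjusted p = 0.000269). Of 29 auxin response factor genes 5 rose (6 adjusted over the list alone): HORVU.MOREX.r2.2HG0150790.1, similar to ARF16, by 2.00 ± 0.251 (adjusted p = 0.000996), HORVU.MOREX.r2.6HG0463500.1, similar to ARF19, by 1.60 ± 0.149 (adjusted p = 0.000146), and HORVU.MOREX.r2.3HG0261550.1, HORVU.MOREX.r2.7HG0549250.1 and HORVU.MOREX.r2.7HG0602930.1. The response factor list had a median of 0.12 (adjusted p = 0.0135, adjusted p = 0.409 with an estimated correlation), with adjusted p = 0.168 without replicate 3 of 3 h and 0.143 without replicate 1 of 0 h. Without a filter on low counts its median turned to -0.0043 (adjusted p = 0.105). The auxin response factor median was 0.0729, 0.0142 and 0.073 without replicates 1, 2 and 3 of 3 h. The auxin transport median was 0.0781, 0.20 and 0.55 without replicates 1, 2 and 3 of 0 h and 0.0594 without replicate 3 of 3 h. Of 11 genes for auxin synthesis and reception 1 fell, over all genes and adjusted over the list alone. It was the receptor gene HORVU.MOREX.r2.4HG0338270.1, similar to AFB5, which went from 62.6 ± 11.5 to 29.0 ± 1.70 CPM (n = 3 each, -1.11 ± 0.149, adjusted p = 0.00158). The receptor gene HORVU.MOREX.r2.1HG0017830.1, similar to TIR1, was at -0.52 ± 0.177 (adjusted p = 0.225). The list had a median of -0.19 (adjusted p = 0.0682, and 0.0462 with the replicate block).

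**Figure D3:**
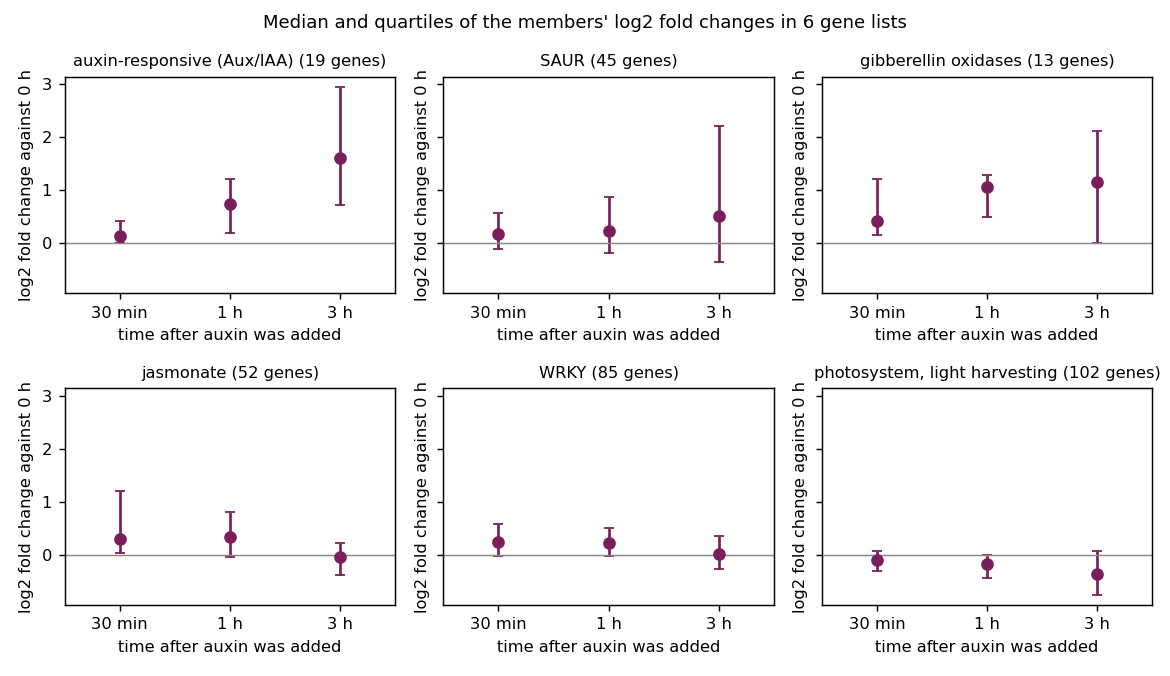
Median (point) and quartiles (bars) of the members' log2 fold changes against 0 h at 30 min, 1 h and 3 h in 6 gene lists. Aux/IAA genes have medians of 0.13, 0.74 and 1.60, jasmonate genes 0.30, 0.33 and -0.04, and photosystem and light-harvesting genes -0.11, -0.18 and -0.36.

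Homologs of rice crown-root regulators were among the genes that rose at 3 h. The LOB domain gene HORVU.MOREX.r2.4HG0339920.1 (4H, 595307482 to 595308336) has rice CRL1 as its first listed rice homolog in the authors' deposited table and is similar to Arabidopsis LBD29. It rose from 14.9 ± 4.24 to 120 ± 23.1 CPM (n = 3 each), a log2 fold change of 3.02 ± 0.262 (adjusted p = 0.000107), and at 1 h it stood at 1.46 ± 0.249 (adjusted p = 0.0808). The first WOX11 homolog HORVU.MOREX.r2.2HG0091310.1 rose by 5.27 ± 0.37 (adjusted p = 2.02e-05). The gene HORVU.MOREX.r2.4HG0315980.1, for which WOX11 is listed second, rose by 3.10 ± 0.359 (adjusted p = 0.000595). The gene HORVU.MOREX.r2.3HG0251360.1, similar to Arabidopsis WOX5, rose by 2.82 ± 0.516 (adjusted p = 0.0125). These were the 3 of 8 WUSCHEL-related genes that rose over all genes and adjusted over the list alone (median 0.34, adjusted p = 0.000197, adjusted p = 0.0502 with an estimated correlation). Of 22 LOB domain genes 7 rose (7 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.000197, adjusted p = 0.0502 with an estimated correlation), among them HORVU.MOREX.r2.6HG0523370.1, similar to LBD16, by 3.40 ± 0.394 (adjusted p = 0.000595). The WUSCHEL-related median was 0.78 without replicate 2 of 0 h and 0.20 without replicate 2 of 3 h. The LOB domain median was 0.0743 without replicate 2 of 0 h and 0.14 and 0.14 without replicates 2 and 3 of 3 h. Other homologs did not pass. The second CRL1 homolog HORVU.MOREX.r2.4HG0276060.1 was at 0.31 ± 0.514 (adjusted p = 0.999), and the second CRL5 homologs HORVU.MOREX.r2.2HG0127160.1 and HORVU.MOREX.r2.5HG0426580.1 were at -0.06 ± 0.481 (adjusted p = 0.999) and 0.88 ± 0.439 (adjusted p = 0.56). The first CRL4 homolog HORVU.MOREX.r2.4HG0278080.1 was at -0.13 ± 0.162 (adjusted p = 0.999). The second CRL4 homologs HORVU.MOREX.r2.3HG0194920.1, HORVU.MOREX.r2.3HG0236690.1 and HORVU.MOREX.r2.5HG0419730.1 were at 0.27 ± 0.13 (adjusted p = 0.515), -0.06 ± 0.362 (adjusted p = 0.999) and -0.17 ± 0.171 (adjusted p = 0.965). Of 21 AP2-like and PLETHORA genes 0 passed over all genes or adjusted over the list alone (median 0.06, adjusted p = 0.813). In the GRAS family 1 of 37 genes rose, over all genes and adjusted over the list alone, the SCARECROW-like gene HORVU.MOREX.r2.2HG0139280.1 by 2.27 ± 0.291 (adjusted p = 0.00117). The SCARECROW gene HORVU.MOREX.r2.5HG0383850.1 was at 0.69 ± 0.194 (adjusted p = 0.113), and the GRAS list had a median of -0.09 with an upward test (adjusted p = 0.955). Of 25 KNOX and BEL homeobox genes, which include shoot meristem regulators, 1 fell, the gene HORVU.MOREX.r2.7HG0595310.1, similar to ATH1 (-2.24 ± 0.302, adjusted p = 0.00162). Both HORVU.MOREX.r2.1HG0059780.1 and HORVU.MOREX.r2.4HG0343610.1 fell with it adjusted over the list alone, and the list had a median of -0.13 (adjusted p = 0.0687).

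Genes for the synthesis and inactivation of other hormones also moved at 3 h. Of 11 cytokinin synthesis genes 4 rose, over all genes and adjusted over the list alone (median 0.53, adjusted p = 2.88e-06, adjusted p = 0.0865 with an estimated correlation). All 4 were of the phosphoribohydrolase (LOG) type, which releases active cytokinin: HORVU.MOREX.r2.1HG0033760.1 rose by 3.63 ± 0.373 (adjusted p = 0.00026), HORVU.MOREX.r2.3HG0235580.1 by 2.04 ± 0.195 (adjusted p = 0.000159), HORVU.MOREX.r2.3HG0222470.1 by 3.09 ± 0.394 (adjusted p = 0.00111) and HORVU.MOREX.r2.4HG0339680.1 by 5.31 ± 0.569 (adjusted p = 0.000349). The family described as phosphoribohydrolase also had 11 tested members, 4 of them higher, and a median of 0.53. The list thus appears to hold this type alone, and it does not compare it with other cytokinin synthesis genes. In the cytokinin response list of 31 genes the cytokinin oxidase gene HORVU.MOREX.r2.3HG0265950.1 rose by 2.96 ± 0.378 (adjusted p = 0.00111), alone on both scales. The response regulator genes HORVU.MOREX.r2.1HG0053020.1 (-1.08 ± 0.161, adjusted p = 0.00331) and HORVU.MOREX.r2.7HG0546700.1 and the cytokinin oxidase gene HORVU.MOREX.r2.7HG0620270.1 fell, with 6 lower adjusted over the list alone (median -0.06, adjusted p = 0.353). Of 13 gibberellin oxidase genes 4 rose: the 2-oxidase genes HORVU.MOREX.r2.2HG0150970.1 (5.99 ± 0.939, adjusted p = 0.00459), HORVU.MOREX.r2.1HG0019640.1 (2.07 ± 0.206, adjusted p = 0.000201) and HORVU.MOREX.r2.1HG0071640.1, for enzymes that inactivate gibberellin, and the 3-beta-hydroxylase gene HORVU.MOREX.r2.3HG0199220.1. In all, 8 rose and HORVU.MOREX.r2.3HG0240680.1 fell adjusted over the list alone (median 1.15, adjusted p = 2.76e-06, adjusted p = 0.141 with an estimated correlation). The ethylene synthesis list had 2 higher and 2 lower of 12, over all genes and adjusted over the list alone (median 0.33, adjusted p = 0.456). The ACC synthase gene HORVU.MOREX.r2.4HG0282950.1 went from 0.430 ± 0.439 to 33.7 ± 0.416 CPM (n = 3 each, 6.10 ± 0.561, adjusted p = 0.000133) and the ACC oxidase gene HORVU.MOREX.r2.5HG0402250.1 rose. The ACC oxidase genes HORVU.MOREX.r2.6HG0513110.1 and HORVU.MOREX.r2.6HG0513090.1 fell, the latter by 1.02 ± 0.189 (adjusted p = 0.013, and 0.0587 and 0.0611 without replicates 2 and 3 of 3 h and 0.0536 without replicate 2 of 0 h). The jasmonate list had a median of -0.04 with an upward test (adjusted p = 0.955). Of its genes the oxophytodienoate reductase gene HORVU.MOREX.r2.1HG0002210.1 rose, over all genes and adjusted over the list alone (adjusted p = 0.0264, and 0.117 without replicate 2 of 0 h, 0.108 without replicate 3 of 0 h, 0.0694 without replicate 2 of 3 h and 0.0982 without replicate 3 of 3 h).

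Photosystem and light-harvesting genes made a large group of falls at 3 h: 19 of 102 fell and 0 rose (39 and 0 adjusted over the list alone). Their median was -0.36 (adjusted p = 9.51e-16, adjusted p = 0.0803 with an estimated correlation). The chlorophyll a-b binding genes HORVU.MOREX.r2.6HG0460170.1, HORVU.MOREX.r2.6HG0460220.1 and HORVU.MOREX.r2.1HG0073480.1 fell by 3.24 ± 0.449 (adjusted p = 0.002), 2.66 ± 0.338 (adjusted p = 0.0011) and 1.98 ± 0.265 (adjusted p = 0.00153, n = 3 each), and near-identical copies of this family may share reads. Outside this list the short-chain dehydrogenase gene HORVU.MOREX.r2.7HG0534500.1 fell by 3.62 ± 0.414 (adjusted p = 0.000559) and the ethylene response factor gene HORVU.MOREX.r2.3HG0249690.1 by 2.91 ± 0.461 (adjusted p = 0.00506). The MYB-related gene HORVU.MOREX.r2.7HG0622940.1, similar to the Arabidopsis clock-associated gene REVEILLE 2, fell by 3.11 ± 0.278 (adjusted p = 0.000127). The flavin-containing monooxygenase gene HORVU.MOREX.r2.3HG0238160.1 fell by 3.10 ± 0.544 (adjusted p = 0.00957, and 0.0514 without replicate 2 of 3 h). The homeobox gene HORVU.MOREX.r2.1HG0068690.1, similar to HAT14, fell by 2.80 ± 0.563 (adjusted p = 0.0214, and 0.0558 without replicate 1 of 0 h, 0.074 without replicate 1 of 3 h, 0.0641 without replicate 2 of 3 h and 0.0954 without replicate 3 of 3 h). Of the 7 clock genes 2 rose, with a list median of 0.52 (adjusted p = 0.000197, adjusted p = 0.218 with an estimated correlation). They were the FKF1 gene HORVU.MOREX.r2.4HG0308090.1 (2.02 ± 0.407, adjusted p = 0.0219, and 0.0961 without replicate 2 of 0 h, 0.108 without replicate 3 of 0 h, 0.0764 without replicate 2 of 3 h and 0.0745 without replicate 3 of 3 h) and the pseudo-response regulator gene HORVU.MOREX.r2.4HG0292520.1 (1.06 ± 0.202, adjusted p = 0.0158, and 0.0586 without replicate 2 of 0 h, 0.0861 without replicate 3 of 0 h, 0.0514 without replicate 2 of 3 h and 0.0777 without replicate 3 of 3 h). The clock genes HORVU.MOREX.r2.3HG0197790.1, HORVU.MOREX.r2.4HG0321070.1 and HORVU.MOREX.r2.5HG0413940.1 rose with them adjusted over the list alone.

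Detoxification, wall and stress lists moved in few members. Of 87 glutathione S-transferase genes 7 rose (12 adjusted over the list alone), with HORVU.MOREX.r2.1HG0040630.1 at 3.57 ± 0.486 (adjusted p = 0.00178), and the list had a median of 0.14 (adjusted p = 1.15e-05, adjusted p = 0.222 with an estimated correlation). The glutathione S-transferase median was 0.24 without replicate 1 of 0 h and 0.22 without replicate 1 of 3 h. Of 223 cytochrome P450 genes HORVU.MOREX.r2.7HG0592200.1, similar to the brassinosteroid-inactivating CYP734A1 (2.66 ± 0.351, adjusted p = 0.00142), HORVU.MOREX.r2.1HG0007630.1, HORVU.MOREX.r2.1HG0067430.1 and HORVU.MOREX.r2.3HG0201730.1 rose. The P450 genes HORVU.MOREX.r2.2HG0080140.1, HORVU.MOREX.r2.2HG0104870.1, HORVU.MOREX.r2.5HG0445010.1 and HORVU.MOREX.r2.7HG0591700.1 fell, and 6 rose and 6 fell adjusted over the list alone (median -0.07, adjusted p = 0.353). Of 126 peroxidase genes HORVU.MOREX.r2.5HG0404500.1 (2.68 ± 0.174, adjusted p = 1.38e-05), HORVU.MOREX.r2.7HG0596240.1 and HORVU.MOREX.r2.3HG0212680.1 rose and HORVU.MOREX.r2.7HG0611980.1 fell. The peroxidase genes HORVU.MOREX.r2.2HG0179140.1 and HORVU.MOREX.r2.4HG0343810.1 rose and HORVU.MOREX.r2.6HG0469330.1 fell with them adjusted over the list alone (median -0.16, adjusted p = 0.173). Of 77 expansin and xyloglucan endotransglucosylase genes the expansin gene HORVU.MOREX.r2.5HG0437890.1 (1.30 ± 0.172, adjusted p = 0.0015) and HORVU.MOREX.r2.2HG0114810.1 rose and HORVU.MOREX.r2.2HG0165790.1 fell by 1.01 ± 0.204 (adjusted p = 0.023, and 0.065 without replicate 2 of 0 h, 0.0555 without replicate 1 of 3 h and 0.108 without replicate 3 of 3 h). The genes HORVU.MOREX.r2.1HG0044660.1 and HORVU.MOREX.r2.2HG0168200.1 rose with them adjusted over the list alone (median -0.11 with an upward test, adjusted p = 0.759). Of 35 UDP-glycosyltransferase genes HORVU.MOREX.r2.7HG0548070.1, HORVU.MOREX.r2.3HG0246000.1 (adjusted p = 0.0131, and 0.0667 without replicate 2 of 0 h, 0.0675 without replicate 3 of 0 h and 0.0617 without replicate 3 of 3 h) and HORVU.MOREX.r2.4HG0326520.1 (adjusted p = 0.037, and 0.132 without replicate 1 of 0 h, 0.153 without replicate 2 of 0 h, 0.0701 without replicate 3 of 0 h, 0.0526 without replicate 2 of 30 min, 0.0579 without replicate 1 of 1 h, 0.0541 without replicate 2 of 1 h, 0.107 without replicate 1 of 3 h and 0.133 without replicate 3 of 3 h) rose, and HORVU.MOREX.r2.5HG0425060.1 joined them adjusted over the list alone (median -0.02 with list adjusted p = 0.111). Among 253 heat shock genes the DnaJ genes HORVU.MOREX.r2.7HG0609890.1 (3.87 ± 0.283, adjusted p = 2.78e-05) and HORVU.MOREX.r2.4HG0318930.1 rose and HORVU.MOREX.r2.3HG0248630.1 and HORVU.MOREX.r2.2HG0098740.1 fell, with 2 and 1 adjusted over the list alone (median 0.01, adjusted p = 0.825). Of 85 WRKY genes HORVU.MOREX.r2.3HG0252360.1 (2.43 ± 0.238, adjusted p = 0.000186), HORVU.MOREX.r2.6HG0497280.1 and HORVU.MOREX.r2.2HG0153650.1 rose, and HORVU.MOREX.r2.7HG0616260.1 joined them adjusted over the list alone (median 0.02, adjusted p = 0.407). Among 81 ethylene response factors HORVU.MOREX.r2.3HG0205590.1, HORVU.MOREX.r2.4HG0337730.1 and HORVU.MOREX.r2.6HG0489770.1 rose and HORVU.MOREX.r2.3HG0249690.1 and HORVU.MOREX.r2.2HG0170410.1 fell, with 9 and 7 adjusted over the list alone (median 0.07, adjusted p = 0.449).

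Growth machinery lists and the marker lists for grain, phloem, xylem and root hair shifted little at 3 h. The photosystem list (leaf) and the KNOX and BEL list (shoot meristem) had also been fixed as tissue markers. As described above, the photosystem list fell, and single KNOX and BEL genes did. No gene of the core histone list passed edgeR over all genes or adjusted over the list alone. The list had a median of -0.19 (adjusted p = 6.51e-06, adjusted p = 0.694 with an estimated correlation, and 0.0536 without replicate 3 of 3 h and 0.113 without replicate 2 of 0 h). The ribosomal protein list, also with 0 members called on both scales, had a median of 0.06 (adjusted p = 0.0329, adjusted p = 0.76 with an estimated correlation). Its adjusted p was 0.297 and 0.0932 without replicates 1 and 2 of 3 h and 0.0513 and 0.682 without replicates 1 and 3 of 0 h. The core histone median was -0.0857 and -0.32 without replicates 2 and 3 of 0 h and -0.31 and -0.0927 without replicates 1 and 3 of 3 h. The ribosomal protein median was 0.12 and 0.0096 without replicates 2 and 3 of 0 h and 0.0253 and 0.11 without replicates 1 and 3 of 3 h. Of 83 cyclin and cyclin-dependent kinase genes the cyclin B1 gene HORVU.MOREX.r2.1HG0045170.1 rose, over all genes and adjusted over the list alone. The kinase inhibitor genes HORVU.MOREX.r2.4HG0340150.1 (-0.88 ± 0.135, adjusted p = 0.00396), HORVU.MOREX.r2.5HG0403220.1 and HORVU.MOREX.r2.6HG0460230.1 (adjusted p = 0.012, and 0.0612 without replicate 3 of 3 h) fell on both scales (list median -0.04, adjusted p = 0.571). Grain storage and amylase genes (15) had a median of 0.01 (adjusted p = 0.782). The 1 that rose, on both scales, was HORVU.MOREX.r2.6HG0520850.1, whose description, immunoglobulin A1 protease autotransporter, matched the list's words by spelling alone. Phloem genes (8) had a median of 0.01 (adjusted p = 0.577), and the phloem protein gene HORVU.MOREX.r2.3HG0201600.1 rose, over all genes and adjusted over the list alone (1.19 ± 0.255, adjusted p = 0.0307, and 0.0543 without replicate 1 of 0 h, 0.114 without replicate 2 of 0 h, 0.0781 without replicate 3 of 0 h, 0.0516 without replicate 1 of 1 h, 0.0523 without replicate 2 of 1 h, 0.0964 without replicate 2 of 3 h and 0.137 without replicate 3 of 3 h). Xylem and secondary wall genes (53) had a median of -0.12 (adjusted p = 0.343) and root hair genes (5) 0.07 (adjusted p = 0.622), with 0 called in either over all genes or adjusted over the list alone. The median of all tested genes at 3 h was -0.00425.

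Tests between the later times asked when the changes arose. Between 30 min and 1 h, 0 genes differed by edgeR, 736 had an unadjusted p under 0.05 (1246 would with no change) and DESeq2 called 22. As a list, Aux/IAA genes lay higher at 1 h than at 30 min (median 0.64, adjusted p = 5.35e-10, adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone, HORVU.MOREX.r2.1HG0021490.1, HORVU.MOREX.r2.3HG0196550.1, HORVU.MOREX.r2.3HG0199050.1, HORVU.MOREX.r2.3HG0238900.1 and HORVU.MOREX.r2.5HG0432000.1 rose. WUSCHEL-related genes also lay higher (median 0.24, adjusted p = 0.00051, adjusted p = 0.11 with an estimated correlation), with HORVU.MOREX.r2.2HG0091310.1 and HORVU.MOREX.r2.4HG0315980.1 higher adjusted over the list alone. Core histone genes lay lower (median -0.12, adjusted p = 5.33e-05, adjusted p = 0.668 with an estimated correlation), with 0 called adjusted over the list alone.

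Between 1 h and 3 h, 297 genes rose and 221 fell. The GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 rose by a further 3.10 ± 0.237 (n = 3 each, adjusted p = 0.000118), the first WOX11 homolog HORVU.MOREX.r2.2HG0091310.1 by 2.97 ± 0.329 (adjusted p = 0.0011) and the first CRL1 homolog HORVU.MOREX.r2.4HG0339920.1 by 1.56 ± 0.247 (adjusted p = 0.00684). The ACC synthase gene HORVU.MOREX.r2.4HG0282950.1 rose by 4.82 ± 0.514 (adjusted p = 0.000986). The WRKY gene HORVU.MOREX.r2.5HG0400740.1 fell by 2.38 ± 0.179 (adjusted p = 0.000118), its neighbour HORVU.MOREX.r2.5HG0400750.1 by 1.94 ± 0.285 (adjusted p = 0.0044) and the knotted-like homeobox gene HORVU.MOREX.r2.4HG0343610.1 by 2.10 ± 0.335 (adjusted p = 0.00721). Aux/IAA genes had a median of 1.05 (adjusted p = 1.85e-07, adjusted p = 0.255 with an estimated correlation), with 8 higher and HORVU.MOREX.r2.3HG0196550.1 lower. Adjusted over the list alone, 10 rose and HORVU.MOREX.r2.1HG0023530.1 and HORVU.MOREX.r2.3HG0196550.1 fell. Photosystem genes had a median of -0.28 (adjusted p = 6.92e-06, adjusted p = 0.345 with an estimated correlation), with HORVU.MOREX.r2.1HG0073450.1, HORVU.MOREX.r2.1HG0073480.1, HORVU.MOREX.r2.6HG0460220.1 and HORVU.MOREX.r2.7HG0560430.1 lower over all genes and 16 adjusted over the list alone. With the replicate block the count was 1692, 819 higher and 873 lower, and DESeq2 called 1289. The count was 239 and 221 without replicates 1 and 2 of 1 h and 291 and 261 without replicates 2 and 3 of 3 h.

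Between 30 min and 3 h, 378 genes rose and 289 fell. The GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 rose by 4.54 ± 0.254 (n = 3 each, adjusted p = 1.07e-05) and the efflux carrier gene HORVU.MOREX.r2.3HG0236360.1 by 2.44 ± 0.188 (adjusted p = 5.99e-05). Of 19 Aux/IAA genes 11 rose (12 adjusted over the list alone), with a median of 1.56 (adjusted p = 2.32e-16, adjusted p = 0.11 with an estimated correlation). Of 52 jasmonate genes 10 fell and HORVU.MOREX.r2.1HG0002210.1 rose (median -0.36, adjusted p = 8.31e-05, adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone, 16 fell and HORVU.MOREX.r2.1HG0002210.1 and HORVU.MOREX.r2.7HG0551030.1 rose. The JAZ genes HORVU.MOREX.r2.7HG0555360.1 and HORVU.MOREX.r2.7HG0555340.1, neighbours on chromosome 7H, fell by 5.63 ± 0.74 (adjusted p = 0.00166) and 4.28 ± 0.737 (adjusted p = 0.00866). The LOB domain list had a median of -0.19 while its test pointed up (adjusted p = 0.0091, adjusted p = 0.181 with an estimated correlation, and 0.106 with the replicate block). In it 6 genes rose, and 8 rose and HORVU.MOREX.r2.4HG0345350.1 fell adjusted over the list alone. With the replicate block 1584 genes passed, 750 higher and 834 lower, and DESeq2 called 1334. The count was 353 without replicate 2 of 30 min and 397 and 364 without replicates 2 and 3 of 3 h.

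Genes called early mostly stayed up. Of the 24 genes that rose at 1 h, 20 also rose at 3 h, the GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 rose at all 3 times, and no gene was called in opposite directions. The other 4 of the 24 differed between 3 h and 1 h by a test of that difference. The WRKY gene HORVU.MOREX.r2.5HG0400740.1 stood at 1.82 at 1 h and -0.56 at 3 h (adjusted p of the difference 0.000118), the ACC oxidase gene HORVU.MOREX.r2.1HG0017380.1 at 1.44 and 0.46 (0.0255), the oxygenase gene HORVU.MOREX.r2.4HG0343710.1 at 2.02 and 0.07 (0.00215) and the protein kinase gene HORVU.MOREX.r2.5HG0445920.1 at 1.36 and 0.54 (0.0292). Independent lists of these sizes would share 0.403 genes, and 20 draws of unchanged groups against the same controls shared 0 genes on average and at most. These draws called 0.25 genes on average and at most 1, so they could share none and do not show what the controls add to lists of 24 and 617. The 3 control libraries cannot be divided into parts of at least 2, so part of the excess may come from the shared controls. The overlap was 4, 5 and 3 without replicates 1, 2 and 3 of 0 h, 2, 12 and 2 without replicates 1, 2 and 3 of 1 h, and 7 and 13 without replicates 2 and 3 of 3 h. It was 51 with the replicate number as a block and 91 with DESeq2.

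The authors' deposited table of comparisons held 91, 115 and 1086 genes with an adjusted p under 0.05 at 30 min, 1 h and 3 h against 0 h. It also held 22 at 1 h against 30 min, 1291 at 3 h against 1 h and 1335 at 3 h against 30 min. All 1, 24 and 617 genes called here against 0 h were among those of the authors' deposited table, as were 515 of 518 at 3 h against 1 h and 666 of 667 at 3 h against 30 min. DESeq2 as run here called all 91, 115 and 1086 of the authors' genes against 0 h.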

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

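The test of handling below was chosen only after the result was seen; the tests of the JAZ cluster and of single libraries were not. Each result in this part was picked because the effects at 2 times, both against 0 h, had opposite signs and the difference between the times passed edgeR's or camera's own test, by a rule set after the data were seen.

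Jasmonate genes were weighed as a pattern. Their median of 0.30 at 30 min and 0.33 at 1 h against -0.04 at 3 h gave a difference of -0.357 between 3 h and 30 min (adjusted p = 8.31e-05) and of -0.457 between 3 h and 1 h (adjusted p = 0.00755). These were adjusted p = 0.345 and adjusted p = 0.481 with an estimated correlation. The JAZ gene HORVU.MOREX.r2.7HG0555360.1 differed by -5.63 between 3 h and 30 min (adjusted p = 0.00166). A tandem cluster of 7 JAZ genes lies on chromosome 7H (106562361 to 106760699). Reads shared within it could raise several members at once, but without the cluster the other 45 genes had a median of 0.20 (adjusted p = 4.68e-05, adjusted p = 0.274 with an estimated correlation), which at the preset correlation argues against the cluster as the whole source. A single library is argued against at the same preset correlation by the highest adjusted p over the 12 fits that left out 1 library, 6.05e-07. The whole list had adjusted p = 0.0865 with an estimated correlation. Handling at the change of solution and a response to auxin or to the loss of NPA cannot be told apart: a short-lived rise, with its later difference of -0.357, is what each would give, and no untreated crowns of the same age were sampled.

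The WRKY gene HORVU.MOREX.r2.5HG0400740.1 differed by -1.72 between 3 h and 30 min (adjusted p = 0.00037) and by -2.38 between 3 h and 1 h (adjusted p = 0.000118). The gibberellin 2-oxidase gene HORVU.MOREX.r2.3HG0240680.1 differed by -2.61 (adjusted p = 0.00195) and -2.30 (adjusted p = 0.00545). Between 3 h and 30 min, the ethylene response factor genes HORVU.MOREX.r2.2HG0157200.1 and HORVU.MOREX.r2.3HG0249690.1 differed by -3.46 (adjusted p = 0.00129) and -4.15 (adjusted p = 0.000617), and the fasciclin-like gene HORVU.MOREX.r2.3HG0230950.1 by -2.08 (adjusted p = 0.0116). The ribosomal protein list had a median difference of 0.175 between 3 h and 30 min (adjusted p = 1.85e-07, adjusted p = 0.419 with an estimated correlation) and of 0.251 between 3 h and 1 h (adjusted p = 1.08e-09, adjusted p = 0.345 with an estimated correlation). Between 30 min and 3 h the auxin transport list had a median difference of 0.552 (adjusted p = 2.22e-05, adjusted p = 0.255 with an estimated correlation), with 6 of 20 genes higher. The auxin response factor list had 0.0912 (adjusted p = 0.00993, adjusted p = 0.424 with an estimated correlation), with 4 of 29 genes higher (HORVU.MOREX.r2.1HG0072210.1, HORVU.MOREX.r2.2HG0150790.1, HORVU.MOREX.r2.3HG0261550.1 and HORVU.MOREX.r2.6HG0463500.1).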

How the results depend on the processing

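Leaving out the 3 libraries with the lowest assigned share was chosen after the result was seen; the other tests of this part were planned. Relative log expression scaling gave 1, 24 and 624 genes at 30 min, 1 h and 3 h against 0 h and 42 list calls. The stricter filter also left every count within 1.5 times. The minimum fold was run for the comparisons between times alone, and left their counts within 1.5 times. Without a filter, 2 genes passed at 30 min, the GH3.3 gene HORVU.MOREX.r2.2HG0106420.1 and the ACC oxidase gene HORVU.MOREX.r2.1HG0017380.1, and the other counts stayed within 1.5 times.

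With the replicate block 3, 66 and 1269 genes passed at 30 min, 1 h and 3 h, 1692 at 3 h against 1 h, 1584 at 3 h against 30 min, 1446 over the time course and 51 in the overlap. The 4 lower genes at 1 h in that fit were HORVU.MOREX.r2.4HG0326230.1, HORVU.MOREX.r2.6HG0460170.1, HORVU.MOREX.r2.7HG0622940.1 and HORVU.MOREX.r2.7HG0622950.1, chosen after their values were seen. With DESeq2 the counts were 94, 115 and 1086, 22 at 1 h against 30 min, 1289, 1334, 1572 and 91. With the 2 groups alone 8 genes passed at 1 h, 377 at 3 h and 318 at 3 h against 30 min, in fits with fewer samples. Without the 3 libraries of lowest assigned share 0 genes passed at 30 min. Of the 42 list calls 4 passed with an estimated correlation and 16 with fry. Except for the fits with fewer samples, the cause was not tested.

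Leaving out 1 library gave 0 (without replicate 1 or 2 of 0 h or replicate 1 or 3 of 30 min) to 3 genes (without replicate 2 of 30 min) at 30 min and 0 to 0 at 1 h against 30 min. At 1 h it gave 3 to 27, with 5, 6 and 5 without replicates 1 to 3 of 0 h, 3, 14 and 3 without those of 1 h and 9 without replicate 2 of 3 h. At 3 h it gave 374 (without replicate 3 of 3 h; 375 without replicate 3 of 0 h) to 627. At 3 h against 1 h it gave 221 to 532, with 239 and 221 without replicates 1 and 2 of 1 h and 291 and 261 without replicates 2 and 3 of 3 h. At 3 h against 30 min it gave 353 to 671, with 353 without replicate 2 of 30 min and 397 and 364 without replicates 2 and 3 of 3 h. Over the time course it gave 297 to 560, with 331 and 297 without replicates 2 and 3 of 3 h. In the overlap it gave 2 to 22, with 4, 5 and 3 without replicates 1 to 3 of 0 h, 2, 12 and 2 without those of 1 h and 7 and 13 without replicates 2 and 3 of 3 h. For list calls it gave 34 to 43.

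Among single lists, the core histone list at 1 h had medians from -0.2861 to -0.0439 over these fits, and its test turned upward without replicate 3 of 1 h (median -0.0555, adjusted p = 0.995). The other 461 of 504 list results without 1 library were the same and 42 no longer passed. Of named-gene results without 1 library 2464 were the same, 109 no longer passed, 4 came to pass and 3 moved. Of list results 9 of 42 no longer passed without a filter, 2 with the stricter filter and 8 without the 3 libraries of lowest assigned share. Some list medians moved by over 1.5 times. They were 0.0019 for ethylene response factor, 0.28 for gibberellin oxidase and 0.0628 for glutathione S-transferase genes at 30 min, 0.26 for LOB domain, -0.0235 for WUSCHEL-related and 0.69 for gibberellin oxidase genes at 1 h, and -0.0043 for auxin response factor genes at 3 h without a filter. With the stricter filter they were 0.11 for SAUR genes at 30 min and 0.72 for WUSCHEL-related genes at 1 h. With the replicate block they were 0.0821 for ethylene response factor genes at 1 h and 0.21 for auxin transport genes at 3 h. Leaving out the 3 libraries of lowest assigned share gave 0.16 for ethylene response factor and 0.73 for gibberellin oxidase genes at 30 min, 0.43 for Aux/IAA, 0.16 for GH3, 0.47 for SAUR, -0.0945 for core histone, 0.16 for clock and -0.0816 for photosystem genes at 1 h, and 0.0118 for auxin response factor and 0.0294 for ribosomal protein genes at 3 h. The planned tests on FPKM values with 1 or 0.1 added were not run, since these values hold 1 number per time.

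Small changes were mostly missed on simulated data: of genes changed by 1.5 times edgeR recovered 0, 2 and 0% and DESeq2, with more false calls, 12, 12 and 10% at 30 min, 1 h and 3 h.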

Other observations

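The families in the next paragraph and the tests of the photosystem genes were chosen only after the result was seen; the regrouping tests were planned.

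Families outside the lists also moved at 3 h against 0 h. Of 13 homeobox-leucine zipper genes 4 rose (Fisher's exact test, adjusted p = 0.00584): HORVU.MOREX.r2.1HG0045880.1 by 2.29 ± 0.334, HORVU.MOREX.r2.2HG0157290.1 by 2.23 ± 0.19, HORVU.MOREX.r2.7HG0537950.1 by 2.10 ± 0.19 and HORVU.MOREX.r2.7HG0537960.1 by 2.22 ± 0.28 (n = 3 each). Of 21 LURP-one genes 4 rose (adjusted p = 0.0296), HORVU.MOREX.r2.3HG0247360.1 by 3.35 ± 0.344, HORVU.MOREX.r2.3HG0247350.1 by 2.43 ± 0.268, HORVU.MOREX.r2.1HG0056720.1 by 1.85 ± 0.307 and HORVU.MOREX.r2.5HG0436630.1 by 1.14 ± 0.242, while HORVU.MOREX.r2.5HG0383940.1 fell by 2.44 ± 0.419. Of 11 VQ motif genes 3 rose (adjusted p = 0.0434), HORVU.MOREX.r2.2HG0090980.1 by 1.66 ± 0.239, HORVU.MOREX.r2.1HG0062640.1 by 1.13 ± 0.199 and HORVU.MOREX.r2.3HG0202420.1 by 1.13 ± 0.184. Of 23 MYB-related genes 3 fell (adjusted p = 0.0435), all similar to REVEILLE genes: HORVU.MOREX.r2.7HG0622940.1 by 3.11 ± 0.278, HORVU.MOREX.r2.6HG0501340.1 by 2.26 ± 0.353 and HORVU.MOREX.r2.7HG0528770.1 by 1.63 ± 0.267. Of 98 MYB genes 6 fell (adjusted p = 0.0126), while HORVU.MOREX.r2.2HG0090570.1, HORVU.MOREX.r2.4HG0316960.1 and HORVU.MOREX.r2.1HG0060940.1 rose by 3.03, 2.66 and 1.18. Of 51 bHLH genes HORVU.MOREX.r2.2HG0131980.1, HORVU.MOREX.r2.4HG0339140.1, HORVU.MOREX.r2.7HG0567160.1 and HORVU.MOREX.r2.7HG0564200.1 fell (adjusted p = 0.0434), while HORVU.MOREX.r2.2HG0164380.1, HORVU.MOREX.r2.4HG0324860.1, HORVU.MOREX.r2.5HG0401530.1, HORVU.MOREX.r2.6HG0472110.1 and HORVU.MOREX.r2.6HG0503700.1 rose (adjusted p = 0.0785). Of 168 glycosyltransferase genes, a wider group than the UDP-glycosyltransferase list, 10 rose (adjusted p = 0.0391), with HORVU.MOREX.r2.6HG0503270.1 highest at 3.94 ± 0.707. Over 413 families and both directions 15 of 826 tests passed. Fisher's test counts each gene as independent, also genes with adjacent identifiers that may share reads. Such are HORVU.MOREX.r2.7HG0537950.1 and HORVU.MOREX.r2.7HG0537960.1, and HORVU.MOREX.r2.3HG0247350.1 and HORVU.MOREX.r2.3HG0247360.1.

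Photosystem and light-harvesting genes fell at 3 h with a median of -0.36. The median of all tested genes was -0.00425. TMM scaling itself brings the bulk of genes near 0, so this median cannot decide on a shift in the scaling of the libraries. A smaller share of green tissue in the 3 h crowns would lower all these genes alike. The comparison was limited to nuclear members with a mean of at least 10 CPM. Among them the 26 chlorophyll a-b binding genes fell further than the 22 others by -0.766 (difference 0.231 ± 0.0589 at 0 h and -0.536 ± 0.401 at 3 h, n = 3 each). This split was chosen after the data were seen, and 17 of 31 genes of the chlorophyll a-b binding family were among the 3 h falls. Their further fall was thus partly set by the choice, so it cannot decide on a smaller share of green tissue. The 3 h replicates were at -0.991, -0.235 and -0.381, each below every 0 h replicate, and the lowest was the library with the lowest assigned share (56.0%). The difference was already lower at 30 min (-0.296, -0.122 and -0.0404) and at 1 h (0.0894, -0.399 and -0.114), so it is not special to 3 h. For the other members too, with a median of -0.349 and 0 of 22 lower by edgeR, the cause stays open. A smaller share of green tissue and a change in the genes cannot be told apart, since tissue was not measured. Time of day also stays open and cannot be told apart from the treatment, as the clock genes had a median of 0.522 and no untreated crowns of the same age were sampled.

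Regrouping the 12 libraries at random tested the counts. Over the time course 2 of 100 groupings, the real one included, gave as many as 574 genes. Chance can be excluded at that share, but the highest other count, 5435, came from a grouping that kept libraries of the same number together for 10 of 12, which points to a structure of the samples (1446 genes with the replicate block). Another grouping with 10 of 12 together gave 0, so what gave the 5435 genes stays open. For list calls 3 of 100 groupings reached 42, so chance can be excluded for that count as a whole. For the overlap 2 of 100 reached 20 (highest other 461). Of the 99 other groupings 97 had an overlap of 0 and 92 had no gene over the time course. The overlap was therefore not tested apart from the presence of calls, and what the shared 0 h libraries add to it stays open. The groupings moved libraries across the replicate numbers, while each real group holds 1 of each number, so chance is excluded only against groupings that ignore these numbers. The 99 other groupings, with 4 to 10 of 12 libraries still together by time, gave 4 to 42 list calls with a median of 19. For pairs of times the 10 groupings of 6 libraries are too few for a share under 0.05. The real counts were 1, 24, 617, 518 and 667 at 30 min, 1 h and 3 h against 0 h, 3 h against 1 h and 3 h against 30 min, each reached by 1 of 10 groupings, with a highest other count of 0. At 1 h against 30 min the real count of 0 was reached by 10 of 10, with a highest other count of 0.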
